A study of Sus scrofa with 325 samples.

How the data were processed

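Total RNA of longissimus lumborum from 325 pigs was extracted with Trizol, labelled singly with Cy3 by a Quick-Amp kit and hybridised to a custom Agilent array, 1 colour and 1 pig per array, per the labels. The deposited values are on a log2 scale with each array's median over all probes at 0. The scanner, background correction, transform and probe filter are not given in the sources used here. The base of the logarithm is not stated either and was inferred from the values. The span from lowest to highest value within an array was 10.3 to 13.4 (median 11.9), which fits a 16-bit scan in base 2 but would exceed the 11.1 natural-log units of such a scan on 319 of 325 arrays. All fold differences rest on that inference. Values down to -5.37 occur, and the lowest value of an array ranged from -5.37 to -2.33. The share of an array's probes within 0.2 of its lowest value was 0.64% at the median and 13.6% at the highest. The lower end of the values thus differed between arrays, and compression of dim probes was not tested. Detection calls were not used here.

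The chip number in the labels was taken as the slide, since it groups the arrays by 8 or 7. Labels placed all arrays in 1 group. Probe identifiers are accessions of source sequences with a position. None of the 14104 source identifiers matched the gene tables used here (Sscrofa11.1 names), so the 24 gene lists and 18 relations between list scores fixed beforehand could not be examined, and each probe was analysed on its own. No identifier was given a gene name by inference.

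Differences between slides were tested with limma 3.58.1 in R 4.3.3 (F test of a slide factor, empirical Bayes, Benjamini-Hochberg adjusted p of 0.05), with the slide labels reassigned at random for a total of 100 splits, the real one included. The share of variance between slides is a one-way random-effects intraclass correlation per probe. Within-slide spread is the SD of residuals from slide means. Probes with 2 modes were found by equal-variance Gaussian mixtures on slide-centred values. A probe was called where the Bayesian information criterion fell by more than 10 from 1 to 2 components, the means lay more than 3 component SDs apart and the smaller component held at least 5%. Each mixture was started from 3 positions and run for up to 300 iterations. Probes named in the text come from a rule fixed before the data were examined: the 25 with the largest within-slide SD, the 15 with 2 modes and the largest separation, and the 10 with the largest share of variance between slides, of which only a few are printed. The correlation of probes from 1 source sequence, the linked sets at r of 0.8, and the comparison of identifier series were added after the data were seen. Single-value permutation tests used 100000 resamples. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 were used.

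The code was tested on simulated data. With slide SDs of 0.3 and 0.6 times the SD between pigs, the slide test recovered 27 and 100 of 100 changed probes among 15198, with 8 false calls. The 2-mode search recovered 32 of 50 balanced mixtures at a separation of 4 SDs and 49 of 50 at 6 SDs, with 0 false calls, so modes 4 SDs apart are missed in part. The simulated values were normal and the smaller mode held 50 or 25%. Recovery of smaller modes of 5 to 10%, and false calls on skewed values, were not tested. A simulated share of variance of 0.25 was estimated at 0.245 (median of 2000 probes). Alternatives fixed beforehand were quantile normalization, leaving out the dimmest 25% of probes, leaving out the 16 arrays of lowest median correlation, no slide centring, subsets of slides, a mean over probes of 1 source sequence, and a smaller separation. Leaving out slide 1, the identifier series as a covariate and 1 probe per source sequence were added later.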

Results

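Muscle RNA from 325 pigs was measured, 1 array per pig. The animals, females and barrows (castrated males), came from a second-generation intercross of a Pietrain-type sire line with a synthetic sire line, bred for mapping of quantitative trait loci. Longissimus lumborum is the loin muscle along the lumbar spine. Every array carried 15198 probes, designed from 14104 source sequences. The arrays lay on 41 slides, 38 of them with 8 arrays and 3 with 7. The labels give 1 tissue and no sex, age, line or trait for any pig, so the data hold 1 group and no contrast between groups. What they do measure is how far each transcript varied between pigs, how transcripts varied together, and how much of the variation followed the slide. No probe identifier was paired with a gene name here, so probes are given by identifier and their functions are left open. The number of arrays limits the precision, and pigs of 1 intercross can be related, so they are not fully independent samples.

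Most probes varied little between arrays and a small number varied widely. With 1 array per pig and no technical replicate, the spread holds both the differences between pigs and the measurement error, which were not separated. The median within-slide SD was 0.23 on the log2 scale, a factor of 1.17, with 5th and 95th percentiles of 0.11 and 0.54 over the 15198 probes (284 residual degrees of freedom each). An SD over 0.5 was found for 1049 probes, 6.90% of the array, and an SD over 1 for 32. Dim probes varied more. The median SD was 0.38 in the dimmest 25% of probes and 0.16 in the brightest 25%. The 25 most variable probes had SDs from 1.04 to 1.99, and 14 of them split into 2 modes by the criteria given in the processing account. The widest was CB286695.1_1794 (SD 1.99, n = 325 pigs), followed by CF175718.1_2364 (SD 1.37, n = 325). Without slide centring 15 of the 25 stayed among the 25 most variable. Among the 25, 9 belonged to the largest set of linked probes described below, and 10 had over 40% of their variance between slides.

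Some probes were fitted better by 2 components than by 1 across pigs. Of 15198 probes, 298 (1.96%) had 2 modes in the slide-centred values. The largest set of linked probes described below held 110 of the 298, so the calls are not all separate findings. In 250 of the 298 the smaller mode held 5 to 10% of pigs, a share that the simulation did not cover, and in 8 it held 40 to 50%. After slide centring the widest separation was that of BP435831.1_1696, 6.09 component SDs, with 5.84% of pigs in the smaller mode. Before centring it was 7.65, below the 15.6 of CF175718.1_2364. Only 169 of the 298 were found again after quantile normalization and 228 without the 16 arrays of lowest correlation, so membership of this list moved more than its size. The count rose to 1052 without slide centring, with 229 shared, and to 560 at a separation of 2 component SDs. Of the 298 probes, 26 had another probe on the same source sequence, and that other probe was also called for 2 of them. The median r with the other probe was 0.229, under 0.2 for 12 of the 26 and at least 0.8 for 6, against a median of 0.772 over all pairs of probes from 1 source sequence.

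Among the 298, 4 probes from different source sequences divided the pigs almost evenly and left an empty interval between the modes in the deposited values. These 4 were singled out after their values were seen, by a smaller mode of at least 40% and a separation over 10 component SDs before slide centring; all lie within the naming rule. For CB286695.1_1794 the fitted component means were 3.65 and -0.36 (component SD 0.31), a 16.1-fold difference, and no pig lay between 1.38 and 3.13. CF175718.1_2364 had component means of 1.60 and -1.17 (SD 0.18), a 6.82-fold difference. AJ938358.1_528 had means of 1.33 and -0.66 (SD 0.19), a 3.97-fold difference, and CF792920.1_1114 had means of 1.99 and 0.53 (SD 0.13), a 2.75-fold difference. The same pigs were divided each time. The 161 pigs in the upper mode of CB286695.1_1794 were also in the upper mode of AJ938358.1_528 and CF792920.1_1114 and in the lower mode of CF175718.1_2364, with no exception among 325 pigs. The upper mode of CB286695.1_1794 held 49.5% of pigs (Wilson 95% interval 44.1 to 54.9%). Because the pigs form separate clusters on these probes, no correlation over all pigs is given for them. The slide accounted for 1.69 to 4.70% of the variance of these 4 probes.

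**Figure D1:**
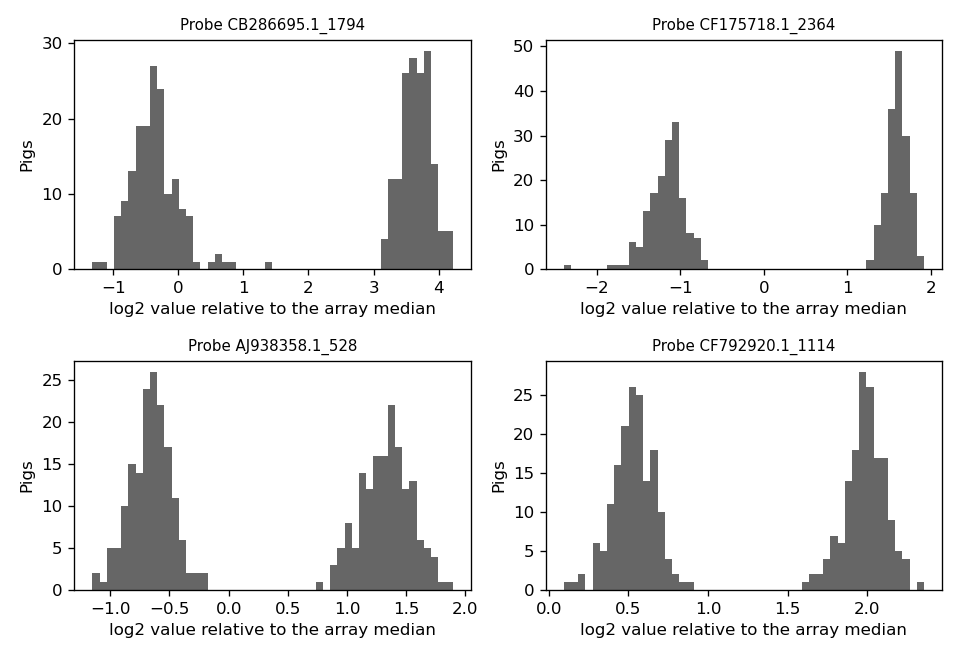
Histograms of the deposited log2 value, relative to the array median, of 4 probes over 325 pigs (y axis, number of pigs). Each probe shows 2 modes with an empty interval between them, from 1.38 to 3.13 for CB286695.1_1794 and from -0.74 to 1.23 for CF175718.1_2364.

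Probes made from the same source sequence gave like readings of the same pigs. Over 1111 such pairs the median Pearson r of slide-centred values was 0.772 (quartiles 0.402 and 0.917) and the median Spearman rho was 0.793. Over 19999 random pairs from different sequences the 5th and 95th percentiles of r were -0.210 and 0.265. In 917 pairs (82.5%) r lay above that 95th percentile. The median was 0.890 for 677 pairs with both probes above the median level of all probes and 0.414 for 243 pairs with both at or below it. A negative r was found for 72 pairs. These correlations are across pigs and the pairs were summarised together, with no test of any single pair.

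Probes varied in linked sets across pigs. At r of 0.8 or more, 2197 probes (14.5%) had at least 1 partner from another source sequence, against 4 probes after 1 shuffle of each probe's values within slides. They formed 372 sets of linked probes, the 4 largest with 868, 110, 74 and 70 probes. Nearly all strong links were positive, 56869 pairs against 10 at -0.8 or below. The set of 868 followed the first principal component, which held 12.4% of the slide-centred variance (r of the set's mean with the component, 0.958). Its links were loose, with a mean r of 0.478 over all its pairs, and a median of 52.6% of its probes' variance lay between slides. Probes with 2 modes made up 110 of its 868 members and a larger share of the set of 74, 32 of 74, against 2 of 70 and 0 of 110 in the other sets. The set of 110 probes varied little (median SD 0.13), had a mean r of 0.838 and had the highest median share of variance between slides of the 4 sets, 57.0%. The sets of 74 and 70 probes had median SDs of 0.39 and 0.40, and slides held only 10.9 and 11.6% of their variance. Their mean r was 0.542 and 0.627, and 0.546 and 0.627 without the 16 arrays of lowest correlation.

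The slide a pig's RNA was hybridised on was associated with nearly every probe. By limma's F test over the 41 slides, 14939 of 15198 probes differed at a Benjamini-Hochberg adjusted p of 0.05. Slides accounted for a median of 28.1% of a probe's variance (5th to 95th percentile 8.62 to 63.4%), against at most 1.06% in 20 random reassignments of arrays to slides. Over 50% of the variance lay between slides for 2097 probes, and over 90% for 15. The highest share was 94.9%, for BF193305.1_328 (adjusted p = 5.806e-165), followed by 94.8% for BQ600620.1_233 (adjusted p = 6.012e-163). The pigs on a slide were not labelled by family, sex or slaughter group, so a difference between slides can hold differences between the animals placed on them.

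Among the 10 probes with the largest share of variance between slides, BQ598889.1_523, singled out after its values were seen, had 2 widely separated levels that followed the slide. Slides held 91.0% of its variance. All arrays of 36 slides lay at 1 level, and 5 slides held both.

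**Figure D2:**
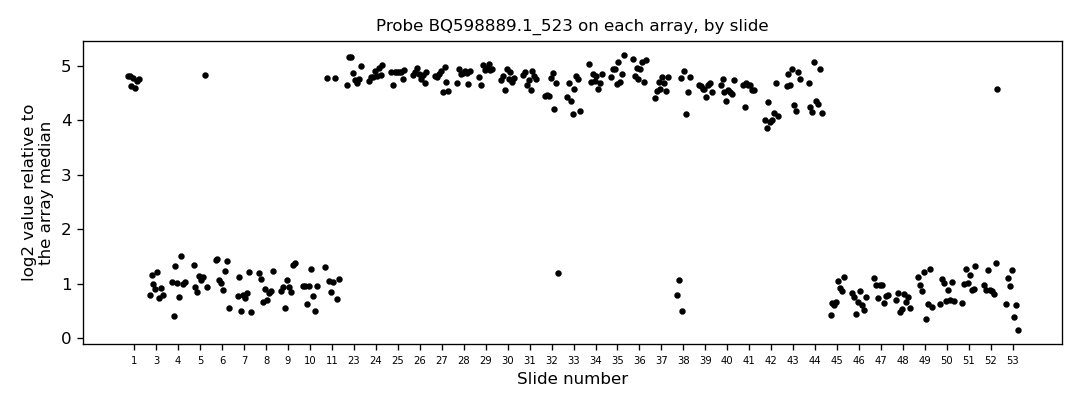
Deposited log2 value of BQ598889.1_523 relative to the array median (y axis) by slide number (x axis), 1 point per array. No array lies between 1.51 and 3.86, and 36 of 41 slides hold 1 level alone.

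Arrays correlated with one another at a median Pearson r of 0.976 over probes, which are not independent replicates, and no array pair was identical (highest r 0.994). Most arrays of slide 1 stood apart. Its arrays had a median correlation of 0.922 with the others, against 0.969 for slide 37, the next lowest, and 6 of its 7 arrays were among the 16 lowest. The other array had a median correlation of 0.979, above the median of all arrays. On slide 1, 807 probes averaged more than 1 log2 unit above the mean of the other slides and 6 more than 1 below.

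**Figure D3:**
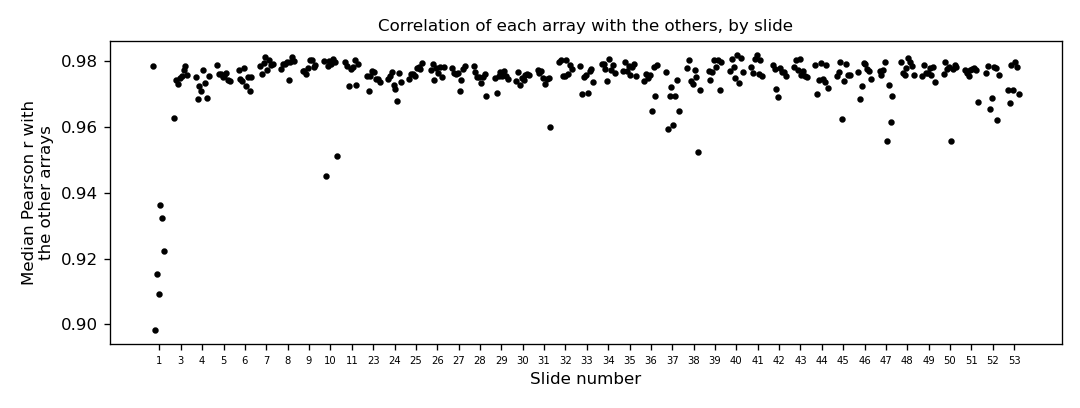
Median Pearson r of each array with the other arrays (y axis, over 15198 probes) by slide number (x axis), 1 point per array. The arrays of slide 1 have a median of 0.922 and those of the other slides medians of 0.969 or more.

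The identifiers of the pigs fall into 3 series, 237 of digits alone, 50 with the prefix M and 38 with the prefix N, whose meaning the labels do not give. Compared within the 30 slides that held more than 1 series, 0 of 15198 probes differed between series by limma at an adjusted p of 0.05, and 964 had an unadjusted p under 0.05. The adjusted count was also 0 after quantile normalization and without slide 1. The unadjusted count was not set against random reassignments of the series, so whether it exceeds chance is open.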

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

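Tests without slide 1, with the identifier series as a covariate or with 1 probe per source sequence, and all alternatives for probe correlations, were chosen after the data were seen. The number of probes differing between slides was 14939 of 15198, too near the total for its stability to say much, and lay between 14816 and 14894 under the 4 alternatives that kept all probes. It was 11190 without the dimmest 25% of probes, where fewer were tested. The median share of variance between slides stayed within 1 SD over resampled slides with quantile normalization, without the dim probes, without the 16 arrays and without slide 1; it was not computed with the covariate. The median within-slide SD of 0.229 moved to 0.276 with no slide centring, which leaves the slide differences in. With quantile normalization it was 0.223 and without the 16 arrays of lowest correlation 0.219, and the cause was not tested. On even-numbered slides it was 0.223 and on slides numbered up to 32 it was 0.219. Each lay more than 1 SD over resampled slides (0.0046) from 0.229, a bound that subsets of slides can pass by sampling alone. Probes with 2 modes numbered 298, but 1052 with no slide centring and 560 at a separation over 2 component SDs, a looser criterion. The median correlation of probes sharing a source sequence, 0.772, moved to 0.862 without the dimmest 25% of probes. Dropping these removes dim pairs, whose median r was lower (0.414 with both probes dim, 0.890 with both bright). The median was 0.802 without the 16 arrays, 0.788 on even-numbered slides, 0.787 on slides numbered 33 and above, 0.788 without slide 1 and 0.732 with no slide centring. For these the cause was not tested, and subsets of slides can differ by sampling alone. By Spearman, a different measure, the median was 0.793. Probes with a partner at r of 0.8 stayed within 1.5 times of 2197 under all 11 alternatives. The 5 probes named in the text as having 2 modes after slide centring kept them in all 20 fits (quantile normalization, dim probes out, 16 arrays out, slide 1 out). Each probe was fitted on its own, so the fits with dim probes out repeat the main fits and add nothing. Array centring on the median changes nothing, since the values are already centred, and is not counted. Each probe was tested on its own in the main analysis. Alternatives for gene lists, relations and scores were not run, since no probe had a gene name. Signal over background was not used here, so how far it limits dim probes is open.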

Other observations

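All tests in this part were chosen, or their bounds set, after the result was seen, except the rank of slide 1 after quantile normalization. The reassignment of arrays to slides was planned, but its bound was written later. At 100 random splits of the arrays into slides, the real one included, 1 gave as many probes as the 14939 found. The highest of the others gave 4. This argues against random placement of arrays as the source of the count, at the smallest share that 100 splits can give. For the identifier series, where the real count was 0, all 100 splits gave as many by construction (highest other 143), which decides nothing. In the slide-centred values 11 probes fitted 3 components at least 2.5 component SDs apart, with 71.3 to 85.6% of pigs in the middle one.

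The 4 evenly divided probes read like a single binary property of the pig. Both modes occurred on 40 of 41 slides, so the slide alone did not set the mode of a pig. The probes were called on slide-centred values, which passes over modes that follow the slide. The mixing within slides therefore partly restates how the probes were picked. A fault or sequence variant at single probes is argued against by the agreement between probes of different source sequences, 100% of pigs for every pair. No source sequence was matched to a gene, so some of the 4 may read the same transcript, and their agreement would then count for less. A candidate explanation is the difference between females and barrows, both of which the population held. The upper mode of the most variable probe held 49.5% of pigs, but no array is labelled by sex, so this stays untested, as does a single inherited factor acting on several transcripts.

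BQ598889.1_523 switched between 2 levels along the slide numbers. Its fitted component means were 4.70 and 0.90 (component SD 0.26), a 14.0-fold difference. It was in the upper mode on 7 of 7 arrays of slide 1, 3 of 72 on slides 3 to 11, 79 of 80 on slides 23 to 32, 92 of 95 on slides 33 to 44 and 1 of 71 on slides 45 to 53, runs that were chosen after the values were seen. The 36 slides with 1 mode alone, where 100000 reassignments gave at most 5, restate the dependence on slide for which the probe was picked. An inherited difference between pigs stays open, since no label says how families were placed on slides. Pig identifiers were not spread evenly over the slides: long stretches of neighbouring identifiers lay mostly on slides 33 to 44. Runs of slide number can therefore also hold blocks of pigs. Hybridisation or washing of a slide as the whole cause is argued against by 8 arrays, on slides 5, 11, 32, 38 and 52, that lay clearly in the other mode than their slide's majority. A batch of samples handled before hybridisation may remain: the majority mode had 3 changes of mode along slide number, where 100000 random orders gave at least 8 (p = 1e-05, the smallest they can give), but no label names an extraction or labelling batch, and a wrong slide label for the 8 arrays was not tested. Mean profiles of neighbouring slides correlated at 0.487 on average over 38 neighbour pairs (permutation p = 1e-05, the smallest possible), against -0.020 over all pairs of slides, across probes. Neither this correlation nor the changes of mode along slide number can tell a handling batch from blocks of pigs placed on neighbouring slides.

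Quantile normalization gives every array the same distribution of values. After it slide 1 kept rank 1 from the lowest of 41 slides in median array correlation (0.932, next lowest 0.970). A Pearson correlation does not change when an array's values are rescaled, so this rank cannot decide on a plain difference in spread. It argues only against a difference in the shape of the distribution as the whole cause. A change of a kind confined to slide 1 is argued against by the correlation of 0.821 over probes between its difference from the other slides and the main axis of variation within those slides. This concerns the direction of the change and not its size. Along slide 1's displacement its lowest array scored 19.4 and its next lowest 89.4, while the highest of 318 other arrays scored 73.8. Pigs with identifiers in the range of slide 1, 155 to 259, did not share its displacement on average. The 19 such pigs on 10 other slides differed from the rest of their slides by -1.86% of slide 1's displacement (95% interval -11.4 to 7.66%, two-sided permutation p = 0.706). Slide 1's own identifiers lay near the ends of that range, and most of the 19 pigs fell between. A source shared with closer neighbours is therefore not excluded. Sample handling and RNA quality were not measured in the data used here and stay open, and no biological explanation was tested.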
